A study of Mus musculus with 3 samples.

How the data were processed

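RNA was sequenced from 3 pools of selected mouse dural cells, each pool from 6 mice and each the only library of its group (PBS, ZOL and ZOL+Ang2), 12 days after inoculation of 4T1-DM cells. Per the labels' protocols, dorsal dura was digested with collagenase VIII and DNase I, cells without CD45 and with CD31 and podoplanin were taken, messenger RNA was amplified at full length from total RNA with a single-cell kit, and libraries were made with a TruePrep kit. How the cells were selected is not given in the sources used here. Groups were taken from the treatment label.

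The deposited files hold RPKM values per gene, which the authors computed from reads per kilobase of gene and a library total that the sources used here do not define. Per the submitters' processing notes, fastp, HISAT2 2.2.1 and featureCounts 2.0.6 were used with the mm10 genome, with no order or role stated. The annotation release and the handling of mate pairs and of reads with several positions are not given in the sources used here. The design had been fixed for a table of counts, so the reads behind the RPKM values were recovered first. Each value times the gene's exon length in GENCODE M21 should be a whole multiple of 1 step per library. With a tolerance of 0.01, 96.9%, 96.4% and 96.2% of the values above 0 in PBS, ZOL and ZOL+Ang2 came out whole. Each file held 54532 genes, of which 37 had no exon length in that annotation and were left out. The recovered reads were 1675542, 16586762 and 9204884, over 16147, 18597 and 15715 genes with reads, and 10389, 14855 and 11850 genes had at least 10 reads. They come to 1.50, 0.701 and 0.785 times the library totals that the RPKM steps imply, so it is open whether they are the authors' counts.

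Low genes sat at even multiples more often than at odd ones (61.2%, 53.3% and 51.1% of genes with 1 to 40 reads), so mates may have been counted singly, and RPKM cannot be told from FPKM by the values. The amplified reads carry no molecular identifiers. All intervals and floors below therefore cover counting error only and are narrower than the true uncertainty.

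Reads were scaled to CPM with TMM factors (1.11, 0.947 and 0.953) computed from the formula with trims of 30% and 5%. Genes with a mean of at least 10 CPM over the 3 libraries (10942) were compared. A log2 fold is the log2 ratio of CPM plus a prior of 5 CPM, which understates differences of low genes. A fold of a named gene is the ratio of CPM without a prior, with an exact 95% binomial interval conditional on both libraries' reads. Where a gene had 0 reads in 1 library, its fold is given as at least the ratio to a floor of 3 reads in that library (1.61, 0.191 and 0.342 CPM in PBS, ZOL and ZOL+Ang2), which bounds counting error and not a loss of transcripts before sequencing. Shares of reads have exact binomial intervals. With 1 library per group no test was run and no p-value is given. Genes at least 2-fold apart were counted as a description of these libraries. Coordinates are mm10, from the same annotation, and gene identifiers are those of the files.

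The groupings, comparisons, filter, prior, naming rule, 36 gene lists and the main alternatives were set before the data were examined. The lists cover the gate, lymphatic and blood endothelium, other cell types of dura, bone, blood and carcinoma, and pathways tied to growth, lipid synthesis, inflammation and stress. A list's median log2 fold was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and stands apart where it lies outside the central 95%. Lists with fewer than 4 measured members (3 lists) were not placed. Random lists ignore that genes of 1 process move together, so a percentile describes how unusual a list is among matched genes and is no probability.

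Named genes were chosen among those with a mean of at least 20 CPM, without unnamed models, clone and pseudogene names, receptor segments of lymphocytes, mitochondrial and ribosomal protein genes. They were taken from the 12 highest and 12 lowest in ZOL against PBS and in ZOL+Ang2 against ZOL, the 6 highest and 6 lowest in ZOL+Ang2 against PBS, and 6 in either direction that went opposite ways in the former comparisons. Added to these are Ptprc, Pecam1, Pdpn, Prox1, Lyve1, Flt4, Ccl21a, Tek, Tie1 and Angpt2, up to 2 highest and 2 lowest members of each list described, and the 2 most abundant members of lists of other cell types. Further members given as examples were chosen after their values were seen.

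The steps were tested on simulated reads drawn from the real means and depths with 200 genes altered. In ZOL against PBS, genes altered 4-fold were recovered past 2-fold in 95.5% of cases with counting error alone and in 71.0% with a biological coefficient of variation of 0.4, at which 17.1% of unaltered genes also passed 2-fold. In ZOL+Ang2 against ZOL the values were 93.5%, 73.0% and 16.3%. In the latter comparison 4.5% of 200 random lists stood apart, and 98% of 50 lists shifted by 2 log2 units. Alternatives were median-of-ratios size factors, total counts, filters of 1 and 50 CPM, a prior of 1 CPM, thinning to the smallest library, named genes alone, and a requirement that the counting interval exclude 1. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.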

Results

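The study profiled RNA of cells taken from the dura mater, the outer membrane around the brain, of mice inoculated with 4T1-DM cells as a model of dural metastasis (4T1 is a mouse mammary carcinoma line). The labels describe cells without CD45 (the product of Ptprc, a leukocyte marker) and with both CD31 (Pecam1, an endothelial marker) and podoplanin (Pdpn), a combination used for lymphatic endothelium, and the series title names meningeal lymphatic vessels as the subject. Mice received PBS, ZOL or ZOL+Ang2, names that the labels leave unexpanded, and the question was how these cells differed between the 3 treatments. The dorsal dura was taken 12 days after inoculation and 6 mice were pooled per group, so each group was 1 library. There were no replicates, no test was possible, and every value below describes 3 libraries and not the spread between animals. The recovered reads came to 1675542 in PBS, 16586762 in ZOL and 9204884 in ZOL+Ang2, so the PBS values were the least precise.

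Ranked expression was close to unrelated between PBS and either other library and related between the latter. Across the 26886 genes with reads in any library, Spearman's correlation was 0.12 for ZOL and PBS, 0.16 for ZOL+Ang2 and PBS and 0.59 for ZOL+Ang2 and ZOL (across genes, which are not independent replicates). The PBS library also had a different make-up. A group of 6 gene models that hold satellite-type repeats took 21.9% of its reads, against 1.06% in ZOL and 3.46% in ZOL+Ang2, and 1 of them, Gm10800, alone took 16.5%. Mitochondrially encoded genes took 12.1%, 1.52% and 1.19% of reads in PBS, ZOL and ZOL+Ang2. Chemoreceptor genes (Olfr, Vmn1r and Vmn2r, receptors of odours and pheromones) took 2.87%, 0.0508% and 0.150%, with reads on 857, 433 and 418 of 1733 genes. Nuclear ribosomal RNA models went the other way, with 1.36% in PBS against 6.74% and 8.17%. Haemoglobin genes held 2.37% of the ZOL+Ang2 reads, 0.0205% in PBS and 0.000573% in ZOL. The exact 95% binomial intervals of these shares are narrow (21.8% to 21.9% for the satellite-type models in PBS) because they cover counting error only.

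**Figure D1:**
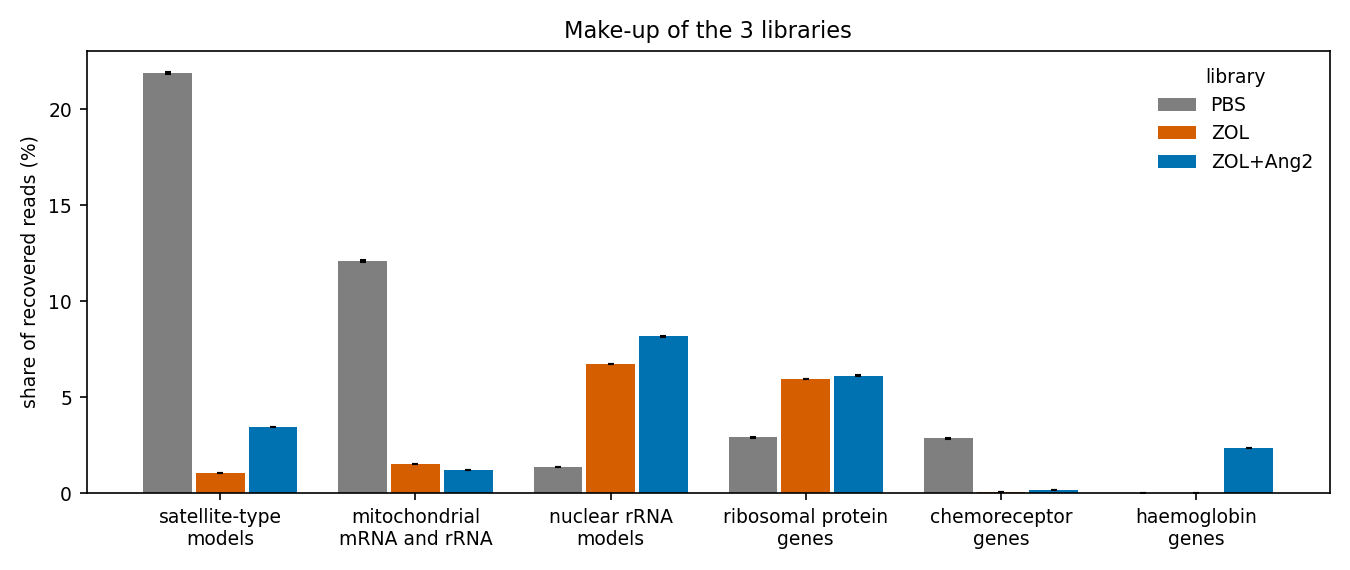
Share of recovered reads (vertical axis, percent) on 6 classes of genes in the PBS, ZOL and ZOL+Ang2 libraries, with exact 95% binomial intervals for counting error as error bars. The satellite-type models took 21.9% of the PBS reads, and haemoglobin genes were visible in ZOL+Ang2 only, at 2.37%.

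The transcripts of the gate markers did not follow the gate evenly. Pecam1 (ENSMUSG00000020717; chromosome 11, 106654217 to 106750628) had 2 reads in PBS, which is 1.08 CPM (reads scaled to library size), 475 CPM in ZOL and 177 CPM in ZOL+Ang2. Pdpn (ENSMUSG00000028583; chromosome 4, 143267431 to 143299564) stood at 18.8, 67.5 and 171 CPM in the same order. Ptprc (ENSMUSG00000026395; chromosome 1, 138062861 to 138175708), whose product the gate excludes, was present in each library at 156, 25.1 and 76.1 CPM. Among lymphatic markers, Lyve1 (ENSMUSG00000030787; chromosome 7, 110850607 to 110863239) had 0 reads in each library, which by counting error alone allows up to 1.61, 0.191 and 0.342 CPM, and Prox1 (ENSMUSG00000010175; chromosome 1, 190118035 to 190170714), the transcription factor that sets lymphatic fate, had 2 reads in PBS and 0 in ZOL and ZOL+Ang2. Flt4 (ENSMUSG00000020357; chromosome 11, 49609263 to 49652739), the receptor of VEGF-C, had 1 read in PBS, 70.9 CPM in ZOL and 23.8 CPM in ZOL+Ang2. Mmrn1 and Reln, further lymphatic genes, were highest in PBS, at 155 and 99.6 CPM against 11.5 and 8.60 in ZOL and 12.0 and 7.87 in ZOL+Ang2. In PBS, values of this size, that of Ptprc included, need not mark expression by lymphatic cells or leukocytes. Cyp2e1, a cytochrome P450 of liver, stood at 820 CPM in that library and Cntnap5a at 259. Ccl21a, the lymphatic chemokine, had 0 reads in PBS, 11.1 CPM in ZOL and 3.88 in ZOL+Ang2, and is uncertain because near-identical gene copies can share its reads. Of the blood endothelial list, whose members ranged widely, Cldn5, a tight junction protein, stood at 1772, 1151 and 326 CPM, Vwf at 972, 1059 and 272, and Bmx at 30.7, 5.80 and 30.6.

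**Figure D2:**
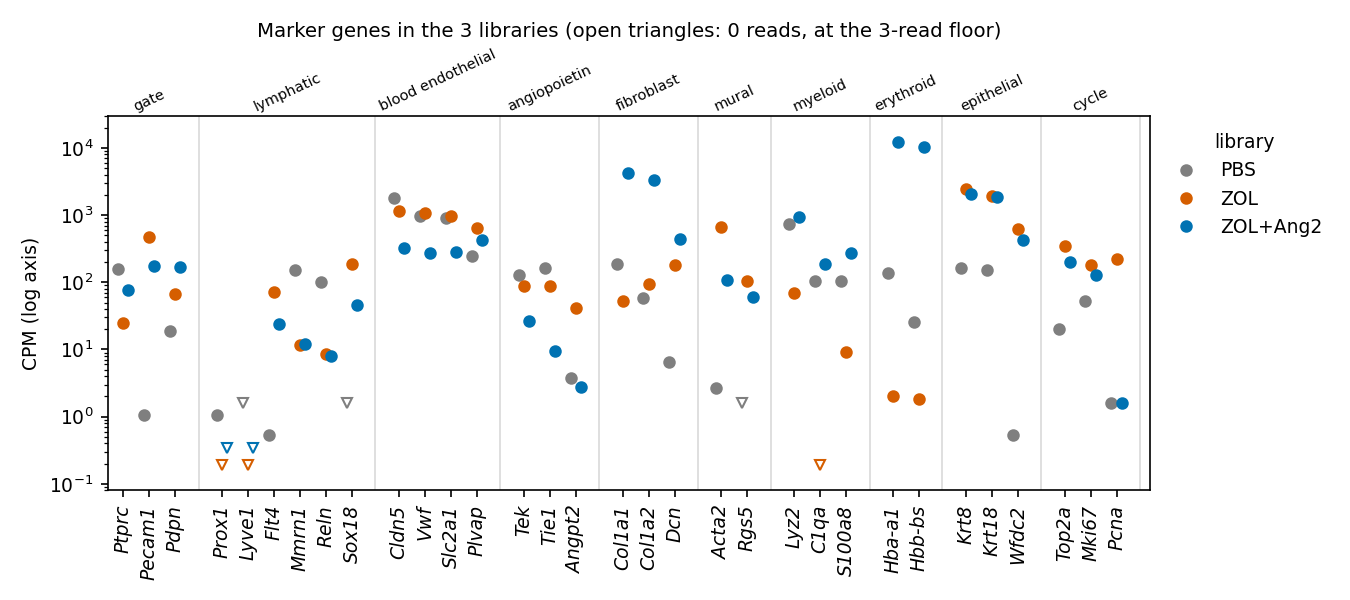
CPM of 32 marker genes (log axis) in the PBS, ZOL and ZOL+Ang2 libraries, grouped by the cell type or process they mark, with open triangles for 0 reads at the level that 3 reads would give. Lyve1 had 0 reads in each library, while Hba-a1 and Col1a1 were highest in ZOL+Ang2, at 12336 and 4281 CPM.

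ZOL against PBS asked how the gated cells differed after ZOL treatment. Relative to other genes, the ZOL library held more reads on cell cycle, epithelial, matrix and sterol synthesis genes. It held fewer on mitochondrially encoded, myeloid, lymphocyte and haemoglobin genes. All 24 genes of the proliferation list were at least 2-fold higher, with a list median 3.04 log2 units above the median of all genes and at percentile 100 of 10000 random lists matched on mean expression. Top2a, the topoisomerase of dividing cells, stood at 20.4 CPM in PBS and 348 in ZOL (17.0-fold higher, 95% counting interval 12.4 to 24.1), and Cdk1 at 4.30 and 231. Of 13 measured genes of the mammary carcinoma and epithelial list, 11 were higher and 1 lower (median 2.11 above all genes, percentile 98.2). Krt8 and Krt18, keratins of simple epithelia, were 14.8-fold higher (interval 13.3 to 16.7) and 12.7-fold higher (11.3 to 14.3), whereas Elf3, an epithelial transcription factor, was 111-fold lower (51.8 to 284).

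Genes of the extracellular matrix remodelling list were also higher, 14 of 20 measured against 1 lower (median 2.11 above all genes, percentile 99.2). Fibronectin (Fn1) stood at 34.4 CPM in PBS and 1155 in ZOL, and the matrix protease Mmp14 had 0 reads in PBS and 129 CPM in ZOL (at least 79.8-fold higher). The exception was tenascin C (Tnc), with 112 CPM in PBS and 0 reads in ZOL. In the mevalonate and sterol synthesis list 14 of 20 measured genes were higher and 2 lower (median 1.90 above all genes, percentile 98.3). Fdft1, which makes squalene, was 219-fold higher (60.6 to 1810.3, from 2 PBS reads), while Cyp51, an enzyme of sterol synthesis, was 2.59-fold lower (2.201 to 3.03). With genes at 0 reads in PBS (7 of these 20) at their bound, the list's median log2 fold was 3.75 against 2.84 as computed. The fatty acid list was split. Of 13 measured genes, 8 were higher, among them Cpt1a and Hadha of mitochondrial oxidation at 101 and 175 CPM in ZOL against 1.91 and 2.15 in PBS, and 4 were lower, among them Acaa2, another enzyme of oxidation (8.91-fold lower, 7.53 to 10.6), and the uptake genes Cd36 (120.0 CPM in PBS, 0.127 in ZOL) and Fabp4 (13.8-fold lower, 10.2 to 18.8). That list's median stood 3.00 above all genes, at percentile 99.9.

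Of the lists that stood lower, the mitochondrially encoded one had 10 of 10 measured genes at least 2-fold lower (median -3.96 relative to all genes, percentile 0). The myeloid list had 10 of 14 lower and 1 higher (median -3.33, percentile 0): lysozyme (Lyz2) stood at 737 CPM in PBS and 68.8 in ZOL, the neutrophil gene S100a8 at 106 and 9.04, and the exception, Cd14, at 66.4 and 175. All 4 measured lymphocyte genes were lower (percentile 0.160), with the B cell gene Cd79a at 232 CPM in PBS and 0 reads in ZOL (at least 1217-fold lower), in a PBS library that also held 2.87% of its reads on chemoreceptor genes. The 15 genes of the lymphocyte list summed to 438 CPM in PBS, 16.6 in ZOL and 0 in ZOL+Ang2. Its 4 measured members therefore passed the filter through PBS and could hardly have been higher, so their count and percentile decide nothing. The erythroid list had 4 of 5 lower (percentile 0.3), led by Hba-a1, which was 67.3-fold lower (46.5 to 101). That list summed to 7.20 CPM in ZOL, so its members passed the filter through other libraries and could hardly have been higher. The blood endothelial list and the immediate early list had members on both sides of 2-fold (5 higher and 3 lower of 16, and 4 higher and 3 lower of 15) and medians -0.83 and -0.84 relative to all genes, at percentiles 0.660 and 0.440. Sox17, an arterial transcription factor, was 7.79-fold lower (6.85 to 8.86) and Ackr1, a venular chemokine receptor, 113-fold higher (31.3 to 935, from 2 PBS reads). The pan-endothelial (8 higher and 2 lower of 17, percentile 13.6), endothelial junction (29.0), fibroblast (45.8), mural (95.2) and bone cell lists (78.9) did not stand apart. Prox1, Lyve1 and Ccl21a lay below the filter of 10 CPM, so the lymphatic endothelial identity list was placed without them. The lymphatic endothelial identity list did not stand apart (5 higher and 3 lower of 13, percentile 31.1), nor did the lymphatic valve (4.81), lymphangiogenic signalling (40.6) or angiopoietin-TIE and FOXO-associated lists (46). Within the latter, Angpt2 was 10.9-fold higher (5.25 to 27.2, from 7 PBS reads), Tek 1.48-fold lower (1.29 to 1.70) and Tie1 1.86-fold lower (1.64 to 2.11).

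Among single genes of at least 20 CPM on average, the highest in ZOL against PBS were Ccdc85b, Apod, Wfdc2, Mtap, Ehd4, Ctnna1, H1f0, Surf4, Acta2, Anxa3, Anxa1 and Tnfrsf12a. Ccdc85b, Ehd4, H1f0 and Surf4 had 0 reads in PBS, which does not show that they were absent, and by counting error alone Ccdc85b was at least 424-fold higher. Apod, a lipocalin, was 722-fold higher (199.8 to 5961, from 2 PBS reads) and smooth muscle actin (Acta2) 252-fold higher (107 to 767, from 5 PBS reads). Anxa1 was 130.0-fold higher (81.6 to 218, from 18 PBS reads) and Wfdc2, an epithelial secreted protein, 1142-fold higher (205 to 45117). The lowest included Vmn1r68, Cyp2e1, Arhgap45, Colec10, Olfr1502, Jakmip2, Cntnap5a, Olfr878, Vmn1r43, Cd79a and Gdap1. Of these, 4 are chemoreceptor genes, the class that took 2.87% of the PBS reads. Vmn1r68 had 2073 reads in PBS and 0 in ZOL (at least 5838-fold lower), and Cyp2e1, a cytochrome P450 of liver, 1524 and 0 (at least 4292-fold lower).

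With genes at 0 reads in 1 library at their bound, list medians as log2 folds were 4.16 for proliferation (3.98 as computed), -2.42 for myeloid (-2.39), -5.92 for lymphocyte (-3.60) and -2.17 for erythroid genes (-1.66). Of 10942 genes with a mean of at least 10 CPM, 5385 were at least 2-fold higher and 3221 lower in ZOL, and 2336 lay within 2-fold. The higher genes made up 62.6% of those past 2-fold, but 47.3% with median-of-ratios size factors, which moved the median of all genes by -1.11 on the log2 scale (from 0.94 to -0.17), and list medians are therefore given relative to all genes. With all libraries thinned to the smallest, 51.2% were higher. Median-of-ratios factors also brought the blood endothelial, lymphocyte and immediate early lists inside the central 95% (percentiles 2.55, 3.12 and 3.06), a filter of 50 CPM the mevalonate list (62.8), a filter of 1 CPM the fatty acid list (95.7) and a prior of 1 CPM the epithelial list (93.9). Of 33 lists placed, 11 stood outside the central 95% of matched lists, and 88 of 1384 genes above 100 CPM in both other libraries had no reads in PBS, so folds against 0 PBS reads are bounds for counting error alone.

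ZOL+Ang2 against ZOL asked how the cells differed when Ang2 was added to ZOL. The ZOL+Ang2 library held more haemoglobin, collagen, macrophage and neutrophil RNA and less endothelial RNA. All 5 measured erythroid genes were higher (median 7.67 above all genes, percentile 100). The 7 genes of that list summed to 7.20 CPM in ZOL and 25184 in ZOL+Ang2. Its measured members passed the filter through other libraries and could hardly have been lower. Hba-a1 (ENSMUSG00000069919; chromosome 11, 32283511 to 32284465) went from 2.04 CPM in ZOL to 12336 in ZOL+Ang2 (6052-fold higher, interval 4287 to 8849), and Alas2, the erythroid enzyme of haem synthesis, from 0 reads to 296 CPM. In the myeloid list 13 of 14 genes were higher and none lower (median 3.51, percentile 100). That list summed to 341 CPM in ZOL, of which Cd14 held 175, so members with few ZOL reads could hardly have been lower. Lyz2 was 13.5-fold higher (12.7 to 14.4), S100a8 30.2-fold higher (25.5 to 36.0), and the complement genes C1qa, C1qb and C1qc stood at 189.5, 255 and 271 CPM against 0, 0.127 and 2.48. Ptprc itself was 3.03-fold higher (2.67 to 3.44). In the dural and arachnoid fibroblast list 8 of 12 were higher and none lower (median 2.09, percentile 100): Col1a1 (ENSMUSG00000001506; chromosome 11, 94936224 to 94953042) was 80.0-fold higher (74.7 to 85.8), Col1a2 35.5-fold higher (33.7 to 37.4), and Mgp, with 522 and 570.1 CPM, lay within 2-fold.

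Endothelial genes were lower. None of 17 measured pan-endothelial genes was higher and 13 were lower (median -1.47 relative to all genes, percentile 0). Pecam1 was 2.68-fold lower (2.53 to 2.83), Icam2 24.1-fold lower (17.5 to 34.1), Clec14a 13.3-fold lower (11.3 to 15.8), and Cdh5, Mmrn2, Sox7 and Sox17 lay within 2-fold. Tie1 and Tek, receptors of the angiopoietin-TIE axis, were 9.24-fold lower (7.400 to 11.7) and 3.36-fold lower (2.92 to 3.88), and Angpt2 was 15.0-fold lower (9.97 to 23.5). CPM are shares of a library. The pan-endothelial list summed to 3674 CPM in ZOL and 1415 in ZOL+Ang2, and the fibroblast list to 1083 and 11616. A change within endothelial cells therefore cannot be told from a smaller share of their RNA. The blood endothelial list had 8 of 16 lower and 1 higher (percentile 0.01), with Cldn5 3.53-fold lower (3.40 to 3.68), the glucose transporter of barrier endothelium Slc2a1 3.47-fold lower (3.33 to 3.63) and Bmx, the exception, 5.27-fold higher (4.14 to 6.76). In the endothelial junction list 7 of 16 were lower and 1 higher (percentile 0.720): occludin (Ocln) stood at 82.1 CPM in ZOL and 0 reads in ZOL+Ang2. Of the lymphatic lists none stood apart: identity had 3 higher and 6 lower of 13 (percentile 9.81), the valve list stood at percentile 7.95 and lymphangiogenic signalling at 10.52. The 13 measured identity genes did not include Prox1, Lyve1 or Ccl21a, so they say little about the core lymphatic markers. Flt4 was 2.97-fold lower (2.56 to 3.46), Pdpn 2.53-fold higher (2.34 to 2.74) and Ccl21a 2.87-fold lower (1.98 to 4.28).

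The immediate early list had 4 of 15 lower and none higher (percentile 0.260), with Egr1 2.91-fold lower (2.60 to 3.26). The mural cell list had 3 of 6 lower and 2 higher (percentile 1.29): Acta2 was 6.22-fold lower (5.82 to 6.65) and the pericyte receptor Pdgfrb 5.74-fold higher (5.08 to 6.49). The MHC list (percentile 1.58) had 11 of 14 within 2-fold, 2 lower (Tap2 and Ciita, at 49.2 and 31.5 CPM against 113 and 82.5) and 1 higher (Nlrc5, 4.51-fold higher, 4.06 to 5.02). The interferon list (percentile 2.44) had 7 of 19 lower, among them Gbp2 at 722 CPM in ZOL and 259.6 in ZOL+Ang2, and 2 higher, Ifit1 (6.47-fold higher, 5.64 to 7.44) and Ifih1 (4.91-fold higher, 4.49 to 5.38). The p53, TGF-beta and bone cell lists stood higher at percentiles 99.2, 98.8 and 97.6, each with members both ways (5 higher and 3 lower of 16, 4 and 3 of 14, and 3 and 2 of 6). Connective tissue growth factor (Ccn2) was 7.58-fold higher (7.10 to 8.08) and osteopontin (Spp1) 2.45-fold higher (2.42 to 2.48), whereas Dmp1, a gene of osteocytes, was 7.98-fold lower (7.10 to 8.99). The proliferation list (1 higher and 9 lower of 24, percentile 3.30) and the mevalonate and sterol list (1 higher and 7 lower of 20, percentile 4.80) did not stand apart, nor did the matrix list (8 higher and 3 lower of 20, percentile 97.1), the angiopoietin-TIE list (13.9) or the epithelial list (58.2).

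The highest single genes were Hba-a1, Hbb-bs, Hba-a2, Hbb-bt, Col6a2, Tnc, Mmp13, Col1a1, Mmp2, Alas2, Ldlrad4 and Sfrp4. The haemoglobin copies Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt, are near-identical, so their split is uncertain. Col6a2 was 941-fold higher (550.0 to 1768), the gelatinase Mmp2 218-fold higher (153 to 324), the collagenase Mmp13 at least 2004-fold higher and Tnc at least 3344-fold higher, the latter pair with 0 reads in ZOL. The lowest were Chgb, Pola2, Adamts1, Fdft1, Tph1, Kif11, Sigirr, Parp3, Lztr1, Mrpl17, Serpina3n and Pcna. Chgb, a granin of secretory granules, had 430.3 CPM in ZOL and 0 reads in ZOL+Ang2 (at least 1258-fold lower). Pola2, Kif11 and Pcna, genes of replication and mitosis, were 1091-fold lower (359 to 5096), 370.3-fold lower (147 to 1060.0) and 138-fold lower (82.1 to 253), although other cycle genes such as Birc5 stood at 187 and 275 CPM.

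With genes at 0 reads in 1 library at their bound, the median log2 fold was 10.54 for erythroid (7.66 as computed) and 3.60 for myeloid genes (3.49). Of the 10942 genes 1769 were at least 2-fold higher and 2718 lower, and 6455 lay within 2-fold. Thinned to the same 1675532 reads, ZOL+Ang2 had reads on 13522 genes and ZOL on 15603. Low values and 0 reads in ZOL+Ang2 therefore need not show lower expression, as transcripts may have been lost before sequencing, which was not tested. Of 638 genes above 100 CPM in both other libraries, 1 had no reads in ZOL+Ang2. Of 33 lists 13 stood apart, and with filter and scaling taken without the PBS library 10 did, the mural (percentile 23.1), bone cell (96.4), interferon (5.59) and endothelial junction (2.60) lists no longer among them. With a filter of 50 CPM the bone cell and p53 lists stood at percentiles 42.2 and 44.3, with median-of-ratios factors the TGF-beta list at 97.2, and with named genes alone the MHC list at 3.58.

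ZOL+Ang2 against PBS asked how cells after the combined treatment differed from those after PBS. Fibroblast genes were higher, 10 of 12 with none lower (median 3.88 above all genes, percentile 100), as were 17 of 20 matrix genes (percentile 99.8), 9 of 13 epithelial genes (percentile 99.4), 16 of 24 proliferation genes (percentile 99.5), 4 of 6 mural genes (percentile 99.9) and all 5 erythroid genes (percentile 99.98). The matrix, epithelial, proliferation and mural lists also held 1, 1, 3 and 1 lower genes. Col1a1 was 22.7-fold higher (20.4 to 25.2), Krt8 12.5-fold higher (11.1 to 13.98) and Hba-a1 89.9-fold higher (79.5 to 102). Lower lists were the mitochondrially encoded (10 of 10, percentile 0), lymphocyte (4 of 4, percentile 0.160), blood endothelial (7 lower and 3 higher of 16, percentile 0.22) and immediate early lists (6 lower and 4 higher of 15, percentile 0.125). The lymphocyte genes passed the filter through PBS and summed to 0 CPM in ZOL+Ang2, so they could not have been higher. Cldn5 was 5.44-fold lower (5.17 to 5.72), Tie1 17.2-fold lower (13.4 to 22.2) and Nr4a1 20.99-fold lower (18.4 to 24.0). The myeloid list did not stand apart (7 higher and 1 lower of 14, percentile 49.6). The highest single genes were Hbb-bs, Gpx3, Col6a1, Hbb-bt, Serpinf1 and Timp1, with Timp1, an inhibitor of matrix proteases, 294-fold higher (135 to 802) and Gpx3 at least 856-fold higher. The lowest were Vmn1r68, Cyp2e1, Arhgap45, Pde1c, Colec10 and Cavin2, with Cavin2, a caveolar protein, 151-fold lower (105 to 226). At their bounds the medians were 4.60 for fibroblast (4.37 as computed), 4.56 for mural (3.74), 3.60 for epithelial (3.22), 3.60 for proliferation (3.31) and -7.58 for lymphocyte genes (-3.83). In all 4831 genes were at least 2-fold higher and 3625 lower (57.1% higher of those past 2-fold, 46.0% with median-of-ratios size factors, which moved the median of all genes by -0.71), and 10 of 33 lists stood apart.

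**Figure D3:**
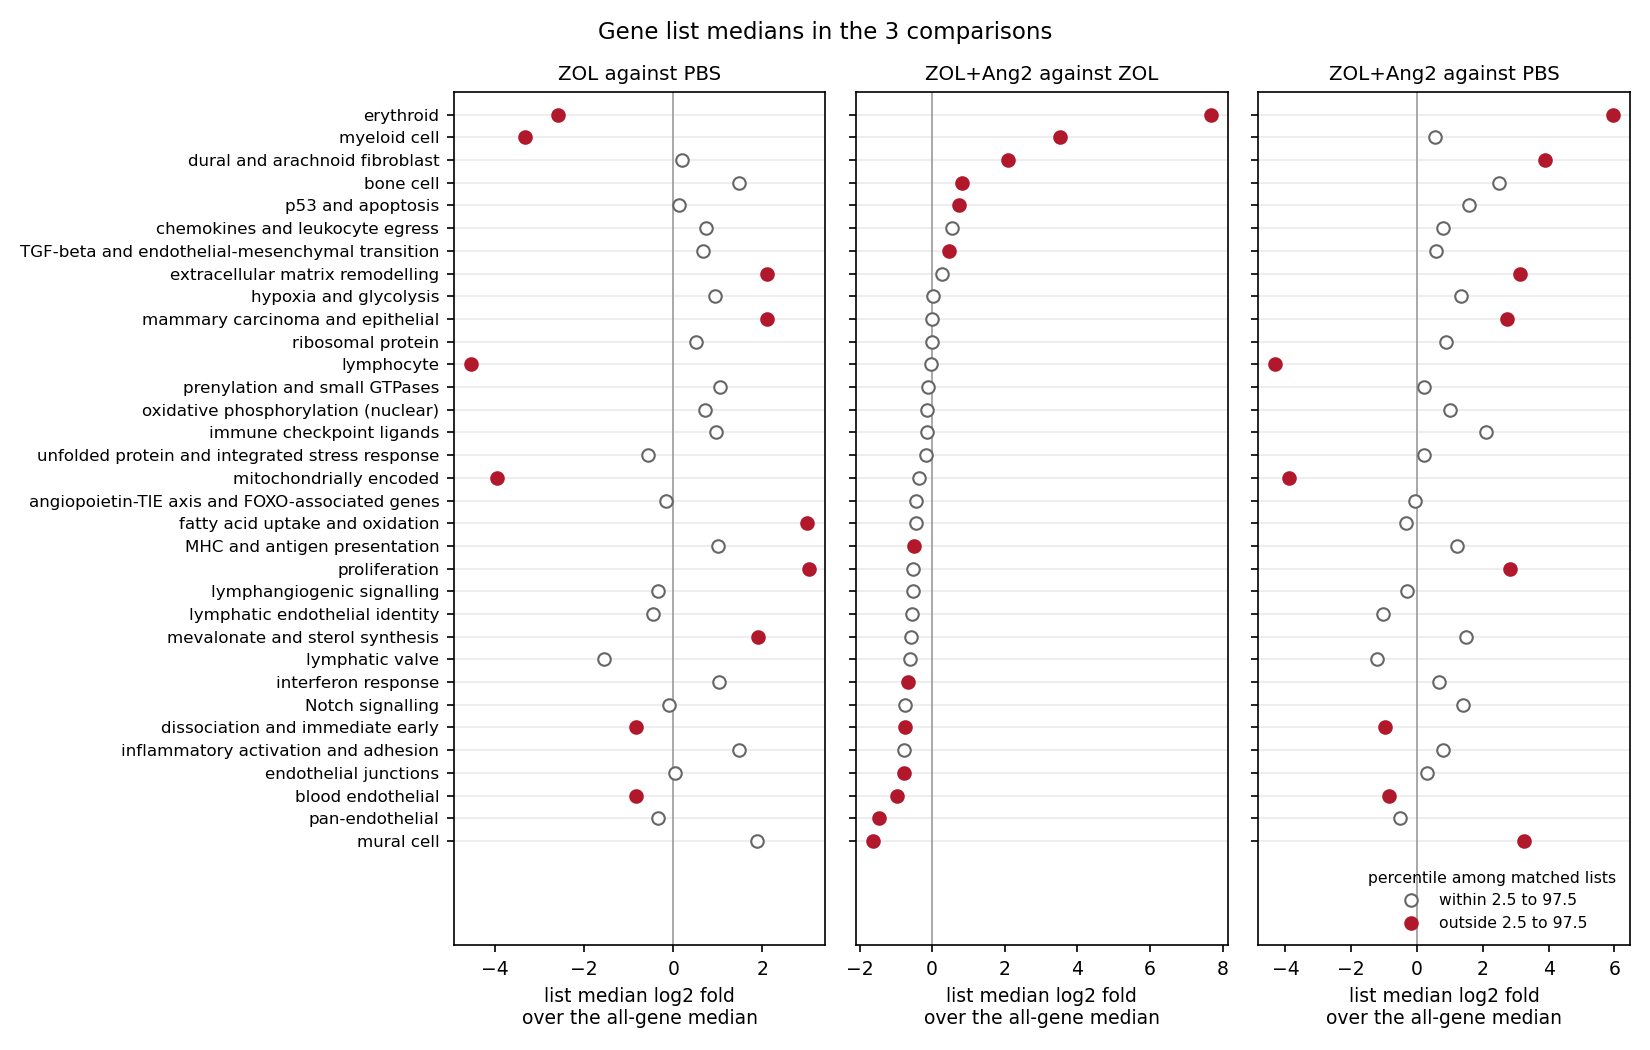
Median log2 fold of each of 33 gene lists relative to the median of all 10942 genes (horizontal axis) in the 3 comparisons, with filled points for lists outside the central 95% of matched random lists. The myeloid list stood at -3.33 in ZOL against PBS and 3.51 in ZOL+Ang2 against ZOL, and the pan-endothelial list at -1.47 in the latter.

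The remaining question was whether ZOL+Ang2 values lay back towards PBS where ZOL differed from it. Genes with high ZOL values and low values in both other libraries included Chgb, Pola2, Fdft1, Tph1, Lztr1 and Serpina3n, and those with the opposite course Hba-a1, Tnc, Ldlrad4, C1qa, Ranbp2 and Nckap1l. Fdft1 stood at 1.08, 236 and 0.684 CPM in PBS, ZOL and ZOL+Ang2, and Nckap1l, a gene of blood cells, at 134, 0.255 and 111. Over all genes compared, the log2 folds against PBS spread as widely in ZOL+Ang2 (SD 2.75) as in ZOL (SD 2.70). By that measure ZOL+Ang2 lay no nearer to PBS than ZOL did. However, PBS was close to unrelated to ZOL and to ZOL+Ang2 across these genes (Spearman's correlation -0.07 for each). Both spreads may therefore mostly reflect the PBS library, and the measure cannot decide whether values returned. Of the 8606 genes at least 2-fold apart in ZOL and PBS, 26.2% lay at least 2-fold back on the PBS side in ZOL+Ang2 (31.6% of the higher and 17.1% of the lower genes). The overlap held 1700 genes for higher then lower and 551 for lower then higher, where independent lists would share 1338 and 521. Both comparisons use the ZOL library, which alone can produce a return. In unchanged simulated libraries no gene passed 2-fold with counting error alone, and 6.12% of 147 and 26.6% of 1933 genes past it returned with biological coefficients of variation of 0.2 and 0.4. The coefficient in these mice is not known, and the folds of ZOL against PBS spread more than in either simulation (SD 2.70 against 0.40 and 0.74). At 0.4 the split was opposite to the observed one (22.8% of the higher and 33.2% of the lower genes). The correlation of the folds was -0.25 and their covariance -1.05, against -0.46 and -0.07 in the simulation at 0.2 and -0.50 and -0.26 at 0.4, and with 1 ZOL library the controls could not be split, so part of the excess overlap may come from the shared library.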

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

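Leaving the PBS library out of filter and scaling, and halving the reads, were chosen after the data had been seen. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out of a group. Of 704 list percentiles under the alternatives, 657 stayed on the same side of the bounds, 21 gained a call, 24 lost theirs on the same side of percentile 50, and 2 lost theirs and came to lie on the other side of 50, still inside the central 95%. Of 1389 folds of named genes, 1360 stayed on the same side of 2-fold, 9 lost it and 20 gained it, and none reversed. The number of lists standing apart stayed between 9 and 15 in each comparison, but not always with the same lists.

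With a filter of 1 CPM, ZOL against PBS had 6404 genes lower, ZOL+Ang2 against ZOL had 2684 higher and 4519 lower, ZOL+Ang2 against PBS had 6843 lower, and 28.5% of genes returned towards PBS. With a filter of 50 CPM the counts were 2040 higher and 551 lower, 512 and 673, and 2001 and 637 in the same order of comparisons, and 19.8% returned. The filters keep different numbers of genes, but the balance moved as well: of genes past 2-fold, 62.6% were higher in ZOL against PBS (53.5% with 1 CPM, 78.7% with 50 CPM) and 57.1% in ZOL+Ang2 against PBS (46.7% and 75.9%), so the majority in the latter turned with the filter of 1 CPM, as it did after thinning (48.3%) and with median-of-ratios size factors (46.0%), and the cause was not tested. The 2 lists on the other side of 50 were the bone cell (percentile 42.2) and p53 (44.3) lists in ZOL+Ang2 against ZOL, with that filter, and the cause was not tested. With named genes alone 2134 genes were lower in ZOL against PBS (70.5% higher of those past 2-fold), and 29.1% returned. The return was 20.7% with median-of-ratios size factors, 24.7% with total counts, 29.7% with a prior of 1 CPM and 22.5% after thinning, and the cause was not tested.

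Without the PBS library, ZOL+Ang2 against ZOL had 1803 genes higher and 2636 lower and 10 lists apart, of which 9 stood apart the same way with all libraries. Lists that lost their call in ZOL against PBS were mevalonate and sterol (percentile 62.8 with a filter of 50 CPM), fatty acid (95.7 with 1 CPM), epithelial (93.9 with a prior of 1 CPM), and blood endothelial (2.55), lymphocyte (3.12) and immediate early (3.06) with median-of-ratios size factors. In ZOL+Ang2 against ZOL, the mural, interferon, bone cell, TGF-beta, MHC and junction lists each lost it under at least 1 setting. The requirement that the counting interval exclude 1 altered no count, with full or halved reads. It could not have done so, because prior and filter keep every gene past 2-fold clear of 1 (lowest limit 1.13 with halved reads), so it says nothing about stability. The depth of the PBS library sets a floor of 1.61 CPM on its values.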

Other observations

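Tests chosen only after their result was seen were the depth test of the PBS library, the percentile of the cell cycle genes, and the separate tests of red cell, fibroblast and myeloid genes.

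Many genes of inflammation and leukocyte traffic were higher in ZOL than in PBS, but so was the median of all genes (0.94, or -0.17 with median-of-ratios size factors), and their lists stayed inside the central 95% of matched lists. Of 13 measured genes of inflammatory activation and adhesion, 10 were at least 2-fold higher in ZOL than in PBS (percentile 93.0), and 6 were lower and 1 higher in ZOL+Ang2 than in ZOL (4.22). Ptgs2, the inducible cyclooxygenase, stood at 0.538, 131 and 0.228 CPM in PBS, ZOL and ZOL+Ang2, and Nfkb2 at 3.00, 185 and 29.2. The chemokine list had 7 of 12 higher and 1 lower in ZOL (percentile 75.8) and 4 each way in ZOL+Ang2 against ZOL (96.8): Cxcl12 stood at 3.23, 189 and 10.4 CPM, and Ccl8, a monocyte attractant, at 68.3, 0 and 80.5. Interferon (12 of 19 higher, percentile 79.9) and MHC genes (11 of 14 higher, 68.2) did not stand apart in ZOL against PBS. Of 5 checkpoint ligands (percentiles 63.6, 39.0 and 86.5 in ZOL against PBS, ZOL+Ang2 against ZOL and ZOL+Ang2 against PBS), 3 were at least 2-fold higher and 1 lower in ZOL than in PBS. Cd274 stood at 0, 33.7 and 24.9 CPM in PBS, ZOL and ZOL+Ang2. Vsir stood at 207, 1.21 and 0 CPM and Arg1, an arginase of myeloid cells, at 1.08, 0 and 121.

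The remaining metabolic, stress and signalling lists did not stand apart in any comparison. In the order of comparisons just given, percentiles were 69.5, 72.9 and 74.6 for hypoxia and glycolysis, 68.4, 27.3 and 55.9 for nuclear genes of oxidative phosphorylation, 31.0, 74.2 and 31.2 for ribosomal proteins, 7.63, 32.6 and 22.2 for the unfolded protein response, 83.1, 33.6 and 40.1 for prenylation and small GTPases, and 44.0, 10.4 and 81.7 for Notch signalling. All 25 ribosomal protein genes lay within 2-fold between ZOL+Ang2 and ZOL. The neural list had 3 measured genes, with Mbp, a myelin protein, at 306, 8.54 and 54.8 CPM, and the renin-angiotensin list 2, Lnpep (104, 48.8 and 85.2) and Agtrap (0, 46.2 and 34.3). The gate genes were too few to place. Gapdh, a common reference gene, had 0 reads in PBS and 15.5 and 16.5 CPM in ZOL and ZOL+Ang2. It was not typical of such genes, as Actb stood at 1522, 6227 and 6780 CPM and Eef1a1 at 1251, 8295 and 6910 in PBS, ZOL and ZOL+Ang2.

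The PBS library had more reads on chemoreceptor genes and satellite-type models. Fewer reads give fewer genes with reads, so 857 chemoreceptor genes in the smallest library, 1.98 times the larger of the other counts (433 and 418), argue against lower depth alone; thinning could only raise that ratio (to 2.77) and was no test. Genomic DNA among the PBS reads is a candidate explanation: families not tied to endothelium (hair keratin-associated, defensin, bitter taste and trace amine receptor genes) stood 19.3 times above the larger of the other libraries. Neither group of genes was evenly covered in PBS. Chemoreceptor reads fell on 49.5% of 1733 genes, with a median of 0 reads per kb against a mean of 8.50, the top gene holding 4.31%. The other families had reads on 20 of 183 genes, the top gene holding 15.4%. An even spread of genomic DNA would not give either pattern alone. Poor amplification of the PBS pool and a biological difference between PBS and ZOL mice were not tested and stay open, since each group is 1 pool.

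Haemoglobin, collagen and macrophage genes were higher in ZOL+Ang2 than in ZOL, and the gate (without CD45, with CD31) would remove red cells, fibroblasts and leukocytes. Scaling was argued against by the share of haemoglobin and collagen reads (0.193% in ZOL and 3.73% in ZOL+Ang2), which allows a library total a shift of at most 0.0549 log2 units, so that their removal, which moved the all-gene median by 0.0091, was no test. A joint presence of all 3 cell types, as predicted before the values were seen, was not met, because the lowest of 3 further marker lists stood 0.207 above all genes; that list was the erythroid one, where 3 of 4 measured members were at least 10 CPM in ZOL already (Fech at 255 CPM), which could hide red cell RNA, a limit set after the value was seen, so for haemoglobin this cannot be told apart. Taken separately, further fibroblast genes (9 of 12 higher and 1 lower, median 3.05 above all genes, 10 of 12 at 10 CPM or more in ZOL, Fstl1 at 136 and 1151 CPM) fit RNA of such cells, as a hypothesis. Of further macrophage and neutrophil genes, 6 of 8 were higher and none lower (median 3.19, Ctss at 41.7 and 381 CPM). Only 1 of 8 was at 10 CPM or more in ZOL, so the others passed the filter through another library and could hardly fall. Among them, Ms4a7 had 0 reads in ZOL and ZOL+Ang2, and Cd53 had 0 reads and 1.37 CPM. Trem2, with 7.32 CPM in ZOL and 0 reads in ZOL+Ang2, did not pass the filter. This list therefore cannot decide on myeloid cells. An effect of Ang2 on the make-up of the dura was not tested and stays open.

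Keratin and cell cycle genes were higher in ZOL than in PBS. Loss of transcripts from the shallow PBS library cannot be told apart, as 88 of 1384 abundant genes and 6 of 24 proliferation genes had no reads in PBS, and the proliferation list's percentile of 100 is the pattern itself and no test of it. Carcinoma cells or their RNA in the ZOL pool are a candidate explanation, as a further epithelial list stood 1.69 above all genes (7 of 10 measured higher, 1 lower), while the gate for CD31 would remove such cells. Cycle genes are used by all dividing cells, so they name no cell type. An effect of ZOL was not tested and stays open.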
